A study of Oryza sativa with 12 samples.

How the data were processed

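RNA from shoots of hydroponically grown rice was measured on 12 arrays of the Affymetrix rice GeneChip, a 1-colour array read with a biotin label. The 4 genotypes were the wild type (WT), the single mutants phr1 and phr3, and the triple mutant that lacks PHR1, PHR2 and PHR3 (phr123), with 3 biological repeats each, according to the labels. The sample titles name the cultivar Nipponbare for WT and give no background for the mutants. All plants had 14 days with 200 µM phosphate and then 7 days without phosphate. The tissue label names leaf, while the protocol names shoots. Plants kept on phosphate and a phr2 single mutant were not analysed here.

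The deposited values are linear signal intensities, 1 per probe set and array. They came from the MAS5 algorithm, per the submitters' processing notes, and its version is not given in the sources used here. On each of the 12 arrays the mean after dropping the highest and lowest values was 500.1, so the values had been scaled array by array before deposit. No aligner or genome build applies to these values. From the files on, every step below was carried out here in R 4.3.3 with limma 3.58.1.

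Of 57381 probe sets, 123 AFFX controls and 64 reporter controls, which carry sequences of common marker genes from other organisms, were left out of the tests. That left 57194 probe sets. Values of 0 were set to 0.1, the smallest step of the files. There were 8 of them, and 0 among the probe sets tested. Signals were taken to log2 with no further scaling, and the 28597 probe sets whose mean log2 signal over all 12 arrays was at or above the median were kept (a signal of 49.4). A linear model with 1 mean per genotype was fitted with lmFit across all 12 arrays, which leaves 8 residual degrees of freedom, and moderated with eBayes with a mean-variance trend. Each genotype was compared with WT and with the other genotypes. A further contrast, called here the departure from the sum, set the phr123 change from WT against the phr1 and phr3 changes added together. Adjusted p-values are limma's with Benjamini-Hochberg correction over the probe sets tested, and 0.05 was the threshold. The p-values measure the spread between these samples. With 3 arrays per genotype, that number limits the precision.

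Where every array of the dimmer genotype had a signal at or below the 95th percentile of the reporter controls of its own array, the change is given as "at least N-fold". This sets the mean of the brighter genotype against the reporter level of the dimmer one. The probe sets of a reporter sequence with signal in phr123, described below, were left out of that percentile after the signal was seen. A log2 change of such a gene is no bound, and its place among the largest changes has no meaning. Where only some arrays of the dimmer genotype lay at or below that level, the log2 change is given, but its size is uncertain.

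Gene names came from the annotation of the array given with the data. It named 1 gene for 22436 of the non-control probe sets, several for 95 and none for 34663. All 17905 genes named were found in the RefSeq table of assembly ASM3414082v1, which was used for symbols, synonyms and gene order only. Among the tested probe sets, 18303 had 1 gene, which made 15469 genes, and 2171 of these carried a symbol. For gene lists, the probe set with the highest mean log2 signal stood for its gene. A probe set with several genes was given no name.

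The genes named in the text were chosen by a rule written before the data were examined. It took PHR1, PHR2 and PHR3, the 10 largest rises and 10 largest falls against WT among probe sets past the threshold, and the phosphate genes fixed by identifier. For comparisons among mutants and for the departure it took the 5 largest of each. All 3 arrays of one genotype had to lie on one side of all 3 of the other. The rule also took up to 4 members of each described list with the smallest adjusted p. It asked for genes with a description; as the annotation had none, a symbol was required in its place. Other genes named are marked as chosen after their values were seen.

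A set of 22 gene lists was fixed by identifier or by keyword before the data were examined. As the annotation holds symbols and no descriptions, the keywords were turned into symbol and synonym patterns after the annotation had been seen and before any comparison was made. The list of phosphatases and RNases that scavenge phosphate matched no gene, and the list of root markers had 2 measured genes. The other 20 were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes and, beside it, with the correlation estimated from the data. Some of these 20 covered only part of what they were fixed for. The membrane lipid list held only MGD1, MGD2 and MGD3. The SPX and PHO1 list had 7 measured of 9 matched genes, and the light reaction list 8 of 35. Families named by a shared symbol were added after the values were seen, and 100 were tested.

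The model, the counts and camera were tested on simulated data with known changes. The means and spreads came from a fit of the real arrays. For camera, random sets of genes with independent noise stood in for the lists. With changes of 0.5, 1 and 2 on the log2 scale planted among 28597 probe sets, 17.9%, 64.2% and 74.2% were recovered for phr1 against WT, with 2 false calls. For phr3 the shares were 11.9%, 58.2% and 84.8%, with 6 false calls, and for phr123 they were 11.9%, 53.7% and 89.4%, with 5.

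Alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, a pseudocount of 16, no filter or the brightest 30% of probe sets, removal of probe sets prone to cross-hybridization, eBayes without a trend or with robust moderation, a requirement of at least a 2-fold change, a fit of only the genotypes compared, the repeat number as a block, each array left out in turn, the mean of all probe sets of a gene and the estimated correlation. List medians under both scalings, the lists of the departure and of phr123 against each single mutant without single phr123 arrays, and a fit in which each mutant had a different WT array as its control were added after seeing the data. Figures were drawn with matplotlib 3.10.9.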

Results

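Transcript levels were measured in shoots of phosphate-starved rice of 4 genotypes, WT, phr1, phr3 and phr123, with 3 arrays each. PHR1, PHR2 and PHR3 are related MYB transcription factors that switch on phosphate starvation genes in rice. All 12 arrays had a trimmed mean signal of 500.1. Their median signal ran from 56.6 to 85.6, the 95th percentile of the reporter controls from 48.4 to 87.6, and 47.5% to 57.1% of probe sets lay above that level. Arrays of the same genotype correlated with r from 0.948 to 0.963 in 12 pairs, and arrays of different genotypes with r from 0.848 to 0.955 in 54 pairs, across probe sets. The first principal component held 49.4% of the variance, the second 7.02% and the third 6.94%. As a sign of RNA quality, the 3' over 5' log2 difference of the GAPDH control was 2.35 ± 0.148 in WT and 1.69 ± 0.133 in phr123 (mean ± SD, n = 3, exact 2-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Those of actin, cyclophilin and ubiquitin gave exact p-values from 0.2 to 1.

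The targeted genes were read first. PHR1 (LOC4332726) had a signal of 1042 ± 146 in WT, 492.7 ± 79.8 in phr1, 1162 ± 36.5 in phr3 and 710.9 ± 126 in phr123 (mean ± SD, n = 3). It fell by 1.08 on the log2 scale in phr1 (SE 0.159, limma adjusted p = 0.00382) and by 0.56 in phr123 (adjusted p = 0.0116). The call in phr123 ended without WT replicate 3 (adjusted p = 0.0545), without the array labelled phr123 replicate 1 (adjusted p = 0.0561) and when arrays were centred on their medians (adjusted p = 0.0802). PHR2 had 1865 ± 147 in WT, 1843 ± 177 in phr1, 2005 ± 89.7 in phr3 and 28.8 ± 13.3 in phr123, at least 28.7-fold lower than in WT (adjusted p = 3.21e-10), and its dimmer probe set was at least 9.67-fold lower (adjusted p = 6.67e-06). PHR3 (LOC4328249) had 439.4 ± 45.8 in WT, 414.7 ± 9.93 in phr1 and 90.37 ± 30.8 in phr3, a log2 difference of -2.34 that did not pass the test in the fit of all genotypes (SE 0.603, adjusted p = 0.0713). It did pass in the fit of phr3 and WT alone (adjusted p = 0.0011), without the array labelled phr123 replicate 1 (adjusted p = 0.000163) and without phr123 replicate 3 (adjusted p = 0.0335). In phr123 the PHR3 signal was 1187 in the array labelled replicate 1, 172.6 in replicate 2 and 118.3 in replicate 3. The log2 difference from WT was -0.60 (adjusted p = 0.469), and it was -1.62 without the array labelled phr123 replicate 1 (adjusted p = 0.000449) and 0.048 without phr123 replicate 3 (adjusted p = 0.959). The sources used here do not place the probe sets against the disrupted part of each gene, and a probe set outside that part checks nothing.

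**Figure D1:**
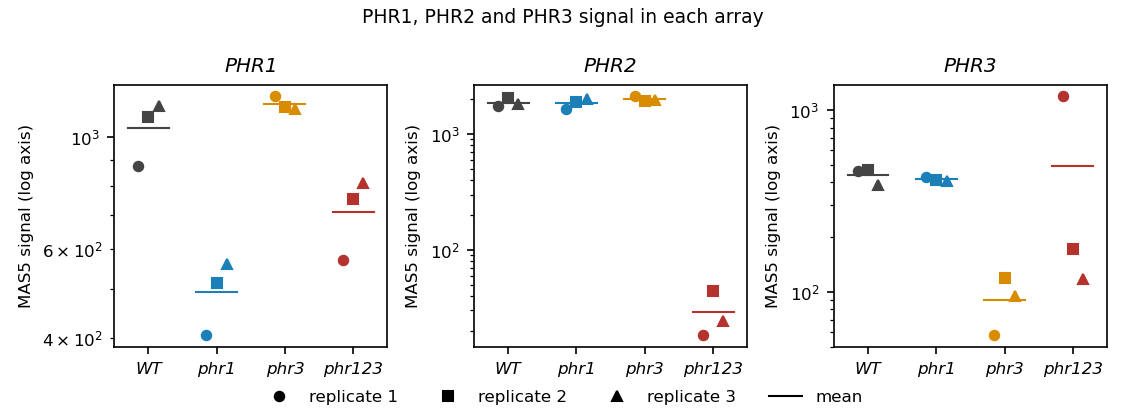
Signal of PHR1, PHR2 and PHR3 in each array by genotype, on a log axis of MAS5 signal, with a marker per replicate and a line at the mean of 3 arrays. PHR2 lay at 28.8 on average in phr123, PHR1 was lowest in phr1, and PHR3 was low in the phr3 arrays and spread from 118.3 to 1187 in the phr123 arrays.

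The comparison of phr1 with WT asked what loss of PHR1 alone changes in starved shoots. SPX2, which encodes an SPX domain protein that senses phosphate status, fell from 12750 ± 1410 to 1993 ± 57.5 (mean ± SD, n = 3), a log2 change of -2.67 (SE 0.118, limma adjusted p = 4.81e-08). Its relative SPX1 fell less, from 12440 ± 391 to 8548 ± 528 (-0.54, SE 0.0735, adjusted p = 0.00212). SPX3 fell from 1414 ± 303 to 450.6 ± 143 (-1.67, SE 0.275, adjusted p = 0.00897), a call that ended without WT replicate 1 (adjusted p = 0.0552), without phr1 replicate 2 (adjusted p = 0.0553) and with eBayes without a trend (adjusted p = 0.0574). SPX5 had 1586 ± 351 against 2826 ± 237 and did not pass (adjusted p = 0.684), though it did in a fit of phr1 and WT alone (adjusted p = 0.0305) and without the array labelled phr123 replicate 1 (adjusted p = 0.00833). Of the 7 measured genes of SPX, PHO1 and phosphate signalling, 3 fell and 0 rose over all probe sets tested, and 4 fell and 0 rose adjusted over the list alone. The list lay lower than other genes, with a median of -0.54 (camera adjusted p = 3.21e-06, and adjusted p = 0.013 with an estimated correlation).

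MGD3, MGD2, PT4 and PT8 fell as well in phr1. MGD3, a monogalactosyldiacylglycerol synthase, fell from 4244 ± 208 to 2865 ± 309 (-0.57, SE 0.0900, adjusted p = 0.00653), and MGD2 fell from 3454 ± 169 to 2130 ± 96.4 (-0.70, SE 0.141, adjusted p = 0.0321). The MGD2 call ended under quantile normalization, with eBayes without a trend and without any 1 of the 3 WT arrays, the 3 phr1 arrays or phr3 replicate 3 (adjusted p from 0.0521 to 0.137). The membrane lipid list held only MGD1, MGD2 and MGD3. Of these 3 genes, 2 were lower over all tested and adjusted over the list alone (camera adjusted p = 0.0164). The call of this list ended without WT replicate 2 (adjusted p = 0.0529) and without phr1 replicate 3 (adjusted p = 0.0516), with adjusted p = 0.281 with an estimated correlation. PT4, a PHT1 phosphate transporter, fell from 4075 ± 331 to 2463 ± 107 (-0.72, SE 0.112, adjusted p = 0.0059). PT8 fell by 0.54 in its brighter probe set (adjusted p = 0.0163) and had -0.44 in the other (adjusted p = 0.251). The PT8 call ended with eBayes without a trend and without WT replicate 1, WT replicate 3, phr1 replicate 1 or phr1 replicate 2 (adjusted p from 0.0501 to 0.0832). Over the PHT1 list, 2 of 6 genes fell over all tested and over the list alone. Its median of -0.05 and mean of 0.0036 differed in sign, and camera gave no call (adjusted p = 0.196).

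Genes outside these lists went both ways in phr1. RR9, a type-A response regulator, rose from 567.5 ± 61.5 to 1614 ± 384 (1.49, SE 0.144, adjusted p = 0.000121), and RR6 rose from 1343 ± 71.9 to 2768 ± 197 (1.04, adjusted p = 5.18e-05). BURP2 rose by 2.89 (SE 0.392, adjusted p = 0.00212), the beta-glucosidase gene BGLU13 by 1.60 (adjusted p = 0.000185), the glutaredoxin gene GRXC15 by 1.28 (adjusted p = 0.00238) and CSLH1 by 0.76 (adjusted p = 0.00212). The CSLH1 call ended when arrays were centred on their medians (adjusted p = 0.147). GRXC10 rose by 2.42 (adjusted p = 0.00975), but not without phr1 replicate 2 (adjusted p = 0.0648), while GRXC7 fell by 0.77 (adjusted p = 0.00123). GRXC1 rose by 1.63, but the call ended without WT replicate 1, WT replicate 2, phr1 replicate 2 or phr1 replicate 3 (adjusted p from 0.0562 to 0.0883). CML16 rose by 0.86, but not without WT replicate 2, WT replicate 3 or any 1 of the 3 phr1 arrays (adjusted p from 0.0615 to 0.0981). PP2C32 rose by 0.82, but not without WT replicate 1 (adjusted p = 0.056) or phr1 replicate 3 (adjusted p = 0.0618). With arrays centred on their medians the calls of CML16 and PP2C32 ended (adjusted p = 0.0743 and 0.138), and with eBayes without a trend those of GRXC1, CML16, PP2C32 and HAK1 (adjusted p from 0.0654 for PP2C32 to 0.122 for CML16). HAK1, a potassium transporter gene, fell by 0.89 (adjusted p = 0.00975), but not without WT replicate 2 (adjusted p = 0.0572) or phr1 replicate 2 (adjusted p = 0.0627). ARP9 fell by 0.76, but not without WT replicate 1, WT replicate 2, phr1 replicate 1 or phr1 replicate 2 (adjusted p from 0.0757 to 0.106) and not in a fit of phr1 and WT alone (adjusted p = 0.0845). ATCase fell by 0.73 (adjusted p = 0.0497), and of the 12 arrays only leaving out the array labelled phr123 replicate 1 kept the call (adjusted p from 0.0667 to 0.177 without each other). It also ended with a pseudocount, with robust moderation and in a fit of phr1 and WT alone (adjusted p from 0.0501 to 0.122).

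Over all 28597 probe sets tested, 128 rose and 139 fell in phr1, 267 in all (62 and 182 with arrays centred on their medians), and 2980 had an unadjusted p under 0.05. At least a 2-fold change was seen in 67 that rose and 21 that fell. Heat shock genes lay lower as a list (median -0.22, or -0.42 with arrays centred on their medians, camera adjusted p = 0.00166, and adjusted p = 0.335 with an estimated correlation), with 2 of 41 lower over all tested and 5 adjusted over the list alone. These 2 were the heat stress factor gene HSFB2A (-0.86, adjusted p = 0.0183) and HSP81-3 (-0.44, adjusted p = 0.0186). The first call ended without WT replicate 2, WT replicate 3, phr1 replicate 1 or phr1 replicate 2 (adjusted p from 0.063 to 0.0869), the second without any 1 of the 3 WT or 3 phr1 arrays (adjusted p from 0.0559 to 0.0917), and both ended with eBayes without a trend (adjusted p = 0.0843 and 0.121). The heat shock list mean relative to WT was -0.0384 in phr1 replicate 1, near the WT arrays (-0.0113 to 0.0084). In phr1 replicates 2 and 3 it was -0.313 and -0.235. None of the 19 cytosolic ribosome genes passed the test, yet the list lay higher than other genes (median 0.12, camera adjusted p = 0.00788, and adjusted p = 0.51 with an estimated correlation). That call ended without WT replicate 2 (adjusted p = 0.406), phr1 replicate 1 (adjusted p = 0.106) or phr1 replicate 2 (adjusted p = 0.0936), and its median turned to -0.08 with arrays centred on their medians. The other lists tested gave no call in phr1 (adjusted p from 0.0865 to 0.791). The count of 267 fell to 121 with eBayes without a trend, 169 without WT replicate 1, 146 without WT replicate 2, 128 without phr1 replicate 2 and 164 without phr1 replicate 3.

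The comparison of phr3 with WT asked the same of PHR3. DREB1B, CBF3 and TIFY11b rose in phr3, while SPX1, SPX2, MGD2, MGD3 and PT4 did not pass the test (adjusted p from 0.189 for PT4 to 0.998 for MGD3). DREB1B, a cold-response transcription factor gene, rose from 36.8 ± 25.0 to 1331 ± 869 (mean ± SD, n = 3), a log2 change of 5.33 (SE 0.667, limma adjusted p = 0.000577), and its relative CBF3 rose from 82.53 ± 26.8 to 1132 ± 394 (3.77, SE 0.345, adjusted p = 4.51e-05). The rise of DREB1B was 4.43 without WT replicate 1 and 5.96 without phr3 replicate 1. The WT mean of DREB1B, 36.8, lay below the reporter level of all 3 WT arrays (51.3, 51.4 and 63.7), so the size of its rise is uncertain. TIFY11b, a JAZ repressor gene of jasmonate signalling, rose from 879.4 ± 71.4 to 4654 ± 1880 (2.32, SE 0.225, adjusted p = 6.99e-05). SPX2 had 12910 ± 1860 against 12750 ± 1410 in WT (0.01) and SPX1 had 11780 ± 520 against 12440 ± 391 (-0.08). SPX3 fell by 1.18 (adjusted p = 0.044), but the call ended with eBayes without a trend and without any 1 of the 3 WT arrays, the 3 phr3 arrays or phr1 replicate 2 (adjusted p from 0.0633 to 0.185).

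Of 32 jasmonate genes, 5 rose and 0 fell in phr3 over all tested, and 10 rose and 1 fell adjusted over the list alone. The list lay higher (median 0.20, or 0.12 with arrays centred on their medians, mean 0.47, camera adjusted p = 0.000319, and adjusted p = 0.108 with an estimated correlation). Among its members, JAZ13 rose from 63 ± 7 to 813.2 ± 717 (3.24, adjusted p = 0.00414), JAZ12 from 764.6 ± 40.6 to 2798 ± 1360 (1.74, adjusted p = 0.0024) and TIFY10a by 0.71 (adjusted p = 0.00286). The rise of JAZ13 was 2.52 without phr3 replicate 2 and 4 without phr3 replicate 1. Heat shock genes went the other way, with 1 higher and 10 lower of 41 over all tested and 3 higher and 13 lower adjusted over the list alone (median -0.28, camera adjusted p = 1.06e-05, and adjusted p = 0.489 with an estimated correlation). HSP24.1 fell from 11710 ± 912 to 4775 ± 665 (-1.30, SE 0.127, adjusted p = 6.99e-05), HSFB2A from 2263 ± 130 to 627.9 ± 72.2 (-1.85, SE 0.157, adjusted p = 2.69e-05) and HSP16.0 by 0.93 (adjusted p = 0.00141). HSFB2B was at least 5.03-fold lower (adjusted p = 0.00233), DJC27, a J-domain cochaperone gene, fell by 1.12 (adjusted p = 0.000613), and HSP18.8 rose by 0.51 (adjusted p = 0.0288). HSP18.6 fell by 1.02, but not without any 1 of the 3 WT arrays, phr3 replicate 1 or phr3 replicate 2 (adjusted p from 0.0572 to 0.0646), nor with eBayes without a trend (adjusted p = 0.0945). CLPB1 fell by 0.93 (adjusted p = 0.0453), and only leaving out the array labelled phr123 replicate 1 or phr123 replicate 3 kept the call (adjusted p from 0.0542 to 0.164 without each other), which also ended with arrays centred on their medians (adjusted p = 0.0775) and with eBayes without a trend (adjusted p = 0.149).

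**Figure D2:**
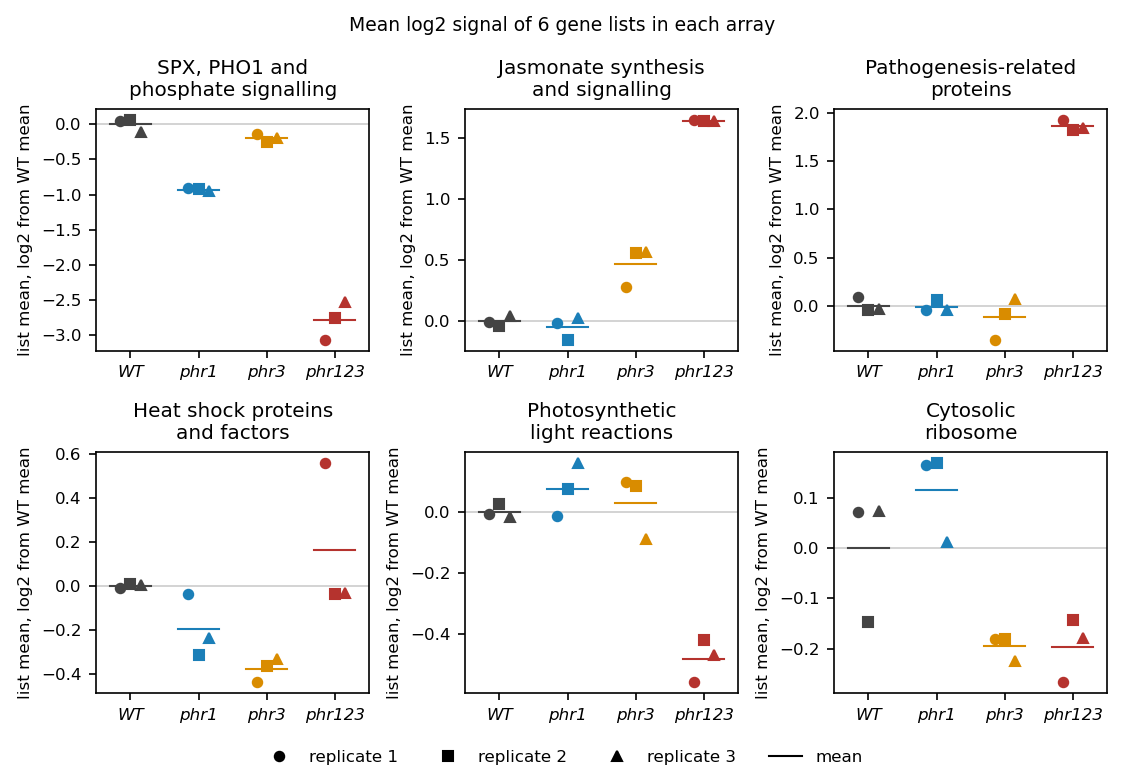
Mean log2 signal of 6 gene lists in each array, as the difference from the mean of the 3 WT arrays, with a marker per replicate and a line at the genotype mean. The SPX and PHO1 list lay from -0.946 to -0.911 in phr1 and from -3.06 to -2.53 in phr123, and the jasmonate list from 0.277 to 0.566 in phr3; the ribosome list in phr1 changes sign when arrays are centred on their medians.

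Dividing tissue markers lay lower in phr3, with 0 of 18 higher and 2 lower over all tested and 4 lower adjusted over the list alone (median -0.35, camera adjusted p = 0.00113, and adjusted p = 0.108 with an estimated correlation). The 2 were mitotic cyclin genes. CYCB1-1 fell from 272.5 ± 47.9 to 101 ± 21.2 (-1.44, SE 0.249, adjusted p = 0.0067), and CYCB2-2 fell by 2.43 (adjusted p = 0.0484), a call kept only without phr3 replicate 3 or the array labelled phr123 replicate 1 (adjusted p from 0.0575 to 0.188 without each other). That call also ended under quantile normalization, median centring, eBayes without a trend and a fit of phr3 and WT alone (adjusted p from 0.0618 to 0.116). None of 19 ribosome genes passed over all tested, 2 fell adjusted over the list alone, and the list lay lower (median -0.20, camera adjusted p = 9.96e-07, and adjusted p = 0.515 with an estimated correlation). Further rises were those of ERG1 (3.67, adjusted p = 0.0067), ABA8OX1, an abscisic acid hydroxylase gene (2.38, adjusted p = 0.00152), WRKY71 (2.00, adjusted p = 0.00346) and RR9 (2.00, adjusted p = 1.03e-05). DREB1G rose by 4.79 (adjusted p = 0.0221), but not without phr3 replicate 2 (adjusted p = 0.112) or phr3 replicate 3 (adjusted p = 0.0744). WRKY24 was at least 6.16-fold higher (adjusted p = 0.0352), but not without any 1 of the 3 WT or 3 phr3 arrays (adjusted p from 0.0719 to 0.14). ERG1 rose by 2.64 without WT replicate 2 and by 4.43 without WT replicate 3, DREB1G had 5.51, 5.65 and 3.20 without WT replicates 1, 2 and 3, and CYCB2-2 had -3.17 without phr3 replicate 3. The means of ERG1 and DREB1G in WT (51.23 and 53.43) and of CYCB2-2 in phr3 (34.47) lay near or below the reporter level, so these sizes are uncertain. LEA19 fell by 1.48 (adjusted p = 0.0417), but not without WT replicate 1 or 2, phr3 replicate 1 or 2, phr1 replicate 2 or 3, or phr123 replicate 2 or 3 (adjusted p from 0.0562 to 0.151). The calls of DREB1G, WRKY24 and LEA19 ended with eBayes without a trend (adjusted p from 0.101 to 0.127), those of DREB1G and WRKY24 with robust moderation (adjusted p = 0.0566 and 0.0526), and that of LEA19 in a fit of phr3 and WT alone (adjusted p = 0.142).

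In all, 360 probe sets rose and 209 fell in phr3, 569 together, and 3530 had an unadjusted p under 0.05. At least a 2-fold change was seen in 151 that rose and 56 that fell. The other lists tested gave no call in phr3 (adjusted p from 0.126 to 0.931). The count was 331 without WT replicate 2, 378 without WT replicate 3, 347 without phr3 replicate 2, 341 without phr3 replicate 3, 298 when arrays were centred on their medians and 299 with eBayes without a trend.

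The comparison of phr123 with WT asked how the starved triple mutant differs from starved WT. SPX1 fell from 12440 ± 391 to 1838 ± 88.3 (mean ± SD, n = 3), a log2 change of -2.76 (SE 0.0735, limma adjusted p = 9.5e-12), and SPX2 to 1890 ± 239 (-2.76, SE 0.118, adjusted p = 8.17e-10). SPX3 fell by 4.72 to 55.67 ± 20.7 (adjusted p = 1.27e-08), and SPX5 was at least 43.5-fold lower, at 31.8 ± 23.3 against 2826 ± 237 (adjusted p = 4.33e-07). The SPX3 mean in phr123 lay near the reporter level of those arrays (54.8 to 71.9), so the size of its fall is uncertain. MGD2 fell from 3454 ± 169 to 97.23 ± 14.3 (-5.16, SE 0.141, adjusted p = 1.14e-11) and MGD3 to 957.5 ± 29.2 (-2.15, adjusted p = 7.31e-10), while MGD1 had a log2 difference of 0.13 (adjusted p = 0.353). PHO1;3 fell from 551.5 ± 167 to 172.4 ± 15.2 (-1.64, adjusted p = 4.33e-05). PHO1;2, which exports phosphate to the xylem, fell by 1.07 in one probe set (adjusted p = 0.000278) and had 0.02 in another (adjusted p = 0.927). SPX4 rose by 0.52 in one probe set (adjusted p = 0.025), and had -0.29 in another (adjusted p = 0.558). That SPX4 call ended without WT replicate 1, WT replicate 3, phr123 replicate 2 or phr123 replicate 3 (adjusted p from 0.0622 to 0.108).

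Of the 7 genes of SPX, PHO1 and phosphate signalling, 6 fell and 1 rose in phr123, over all tested and adjusted over the list alone (median -2.76, camera adjusted p = 0.00145, and adjusted p = 0.0518 with an estimated correlation). The membrane lipid list had 2 of 3 genes lower (median -2.15, camera adjusted p = 0.0557). PHT1 transporters went both ways, with 2 of 6 higher and 1 lower. PT4 fell from 4075 ± 331 to 1117 ± 70.9 (-1.87, SE 0.112, adjusted p = 1.65e-08) and PT8 rose from 2029 ± 87.4 to 4224 ± 140 (1.06, SE 0.0958, adjusted p = 8.04e-07). PT1 had probe sets of opposite direction. One rose from 1520 ± 106 to 3974 ± 422 (1.38, adjusted p = 4.95e-07), and the other fell from 2454 ± 395 to 397.5 ± 179 (-2.70, adjusted p = 5.03e-07). The list's median (-0.12) and mean (-0.06) were below 0, its test pointed up, and it was no call (adjusted p = 0.724). In the phosphate-saving carbon list, AOX1a, the alternative oxidase gene, rose from 1724 ± 225 to 13040 ± 2720 (2.91, SE 0.128, adjusted p = 1.13e-09) and PPDKB fell by 0.88 (adjusted p = 1.41e-06), with 1 higher and 1 lower of 3 (camera adjusted p = 0.7).

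**Figure D3:**
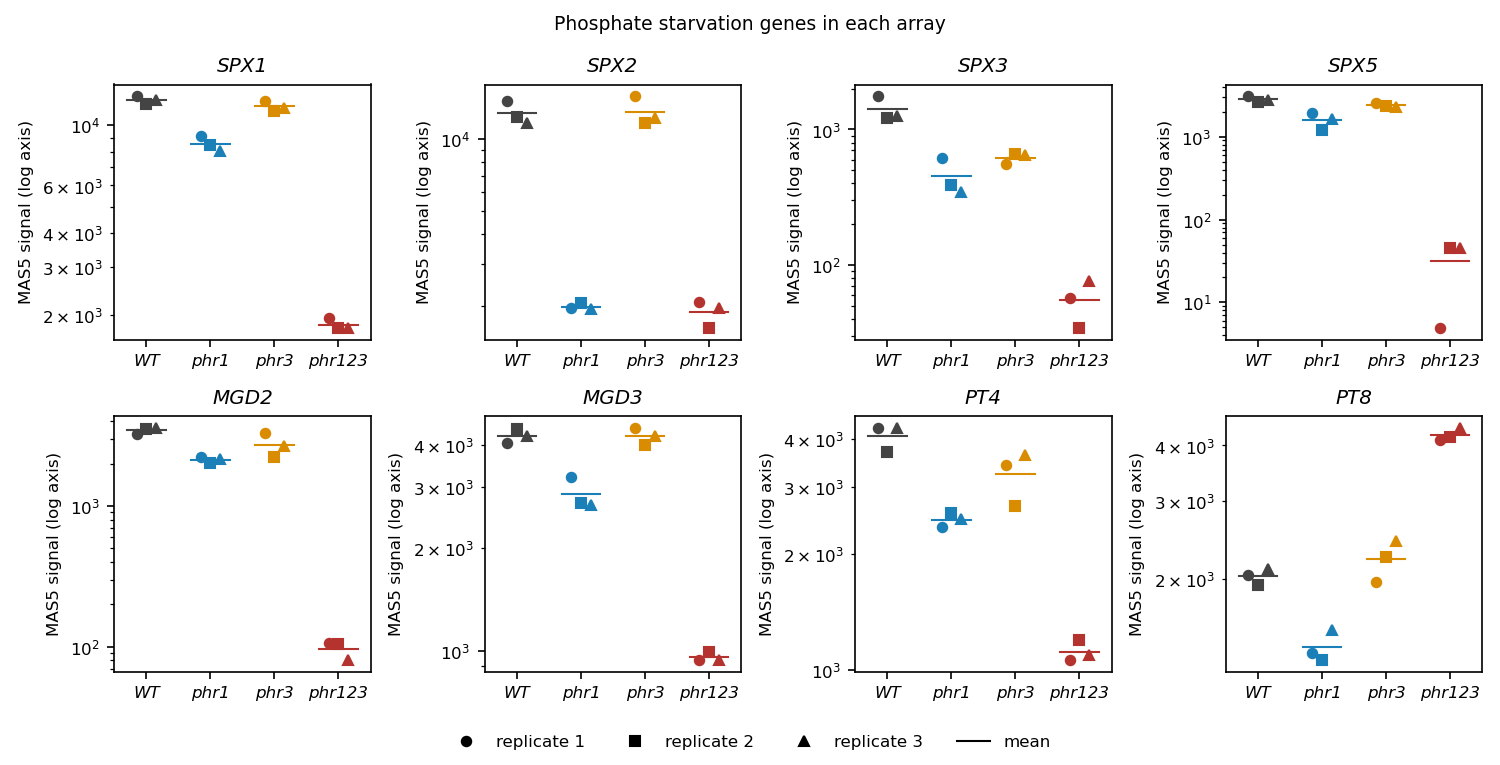
MAS5 signal of 8 phosphate starvation genes in each array by genotype, on log axes, with a marker per replicate and a line at the mean of 3 arrays. SPX2 lay near 1993 in phr1 and 1890 in phr123, the other SPX and MGD genes and PT4 were lowest in phr123, and PT8 was highest there at 4224.

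Of 32 jasmonate genes, 21 rose and 2 fell in phr123 over all tested, 22 and 2 adjusted over the list alone (median 1.24, camera adjusted p = 1.17e-05, and adjusted p = 0.0499 with an estimated correlation). JAZ12 rose from 764.6 ± 40.6 to 12050 ± 402 (3.98, SE 0.262, adjusted p = 3.7e-08), the lipoxygenase gene CM-LOX2 from 189.8 ± 53.5 to 4416 ± 455 (4.57, SE 0.234, adjusted p = 3.83e-09) and AOS2, an allene oxide synthase gene, by 2.99 (adjusted p = 1.43e-07). Among 12 pathogenesis-related genes 11 rose and 0 fell by both adjustments (median 1.53, camera adjusted p = 0.000101, and adjusted p = 0.0701 with an estimated correlation). The chitinase genes Cht8 and CH6 rose from 1155 ± 187 to 17720 ± 1510 (3.95, SE 0.205, adjusted p = 4.36e-09) and by 3.04 (adjusted p = 7.58e-08), and PBZ1 rose from 15580 ± 396 to 51380 ± 3330 (1.72, adjusted p = 1.3e-07). DTC1 was at least 13.5-fold higher (adjusted p = 0.000208), CPS4 at least 19-fold (adjusted p = 0.000214) and MAS, momilactone A synthase, at least 18.8-fold (adjusted p = 3.88e-05). CYP71Z7 rose from 305.5 ± 163 to 13090 ± 190 (5.59, SE 0.362, adjusted p = 3.24e-08). LOX1.1 was at least 29.9-fold and LAC19 at least 17.4-fold higher. LIS, a linalool synthase gene, rose by 5.64, RAA1 by 5.43, OSE727A by 5.14 and pinA by 4.63, with adjusted p from 1.35e-07 for OSE727A to 0.000668 for LIS. Without WT replicate 3 the rise of RAA1 was 4.59. The WT mean of RAA1, 44.9, lay below the reporter level of all 3 WT arrays.

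Of 8 light reaction genes, 7 fell and 1 rose in phr123 by both adjustments (median -0.46, camera adjusted p = 0.0288, and adjusted p = 0.283 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.225, median -0.21). GOS5 fell from 74050 ± 4170 to 38030 ± 1890 (-0.96, SE 0.0768, adjusted p = 2.39e-07), PSB28 and LFNR1 fell by 0.92 each, and PSAG rose by 0.39. All 3 measured genes of the Calvin cycle list fell, CFBP1 by 1.00, rbcS by 0.65 and rcaA1 by 0.37. The list gave no call (camera adjusted p = 0.0651). Its genes were matched by symbol alone, and whether CFBP1 is the chloroplast enzyme that the list asked for was not checked. The rcaA1 call ended under quantile normalization (-0.06, adjusted p = 0.512) and with arrays centred on their medians (adjusted p = 0.106). In starch and sucrose metabolism, 9 of 16 genes fell and 1 rose (camera adjusted p = 0.0578). SUS1, a sucrose synthase gene, fell from 11670 ± 1620 to 1578 ± 447 (-2.91, SE 0.157, adjusted p = 6.12e-09) and AGPS2 by 1.33 (adjusted p = 7.61e-08), while SUS4 rose by 1.47. Of 20 cell expansion genes, 10 fell and 3 rose (median -0.61, camera adjusted p = 0.0557). The expansin gene EXP7 fell from 3970 ± 359 to 89.67 ± 31 (-5.53, SE 0.200, adjusted p = 2.02e-10), EXPB2 by 1.41 and the xyloglucan endotransglucosylase gene XRT5 by 1.11. GER5 fell from 37400 ± 2190 to 496.5 ± 77.3 (-6.25, SE 0.109, adjusted p = 1.46e-13), and MIF3 by 4.74 (adjusted p = 5.18e-05). The fall of MIF3 was -5.39 without the array labelled phr123 replicate 1 and -3.56 without phr123 replicate 2. TDL1B was at least 9.96-fold lower (adjusted p = 2.98e-06), BZIP06 at least 11.2-fold (adjusted p = 7.05e-05) and the Aux/IAA gene IAA14 at least 5.61-fold (adjusted p = 1.53e-05).

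The other lists gave no call in phr123. Of the 15469 genes measured, 4118 had a probe set that rose and 4019 had one that fell, and the list counts are to be read against this. Where a single count is given for a list, it was the same over all tested and adjusted over the list alone. Vascular and secondary wall markers had 8 of 16 lower and 3 higher, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.119). LAC20 (-3.88) and LAC4 (-1.96) fell, and CAD6 rose by 2.04. Nitrogen uptake and assimilation had 4 of 15 higher and 4 lower, or 4 and 5 over the list alone (adjusted p = 0.7), with the ammonium transporter gene AMT3-2 up by 2.38 and the glutamine synthetase gene GLN2 down from 34010 ± 1070 to 20850 ± 2240. Iron and zinc genes had 9 of 30 higher and 6 lower, or 11 and 7 over the list alone (adjusted p = 0.321), with ZIP8 up by 2.68 and NRAMP5 down to 214.9 ± 74.4 from 732.6 ± 72.1. Heat shock genes had 11 of 41 higher and 6 lower (adjusted p = 0.668), with HSFA4D up by 2.37. Flavonoid and phenylpropanoid genes had 1 of 4 higher and 2 lower. Their median was -0.21 and their mean 0.33 (adjusted p = 0.724), and PAL06, a phenylalanine ammonia-lyase gene, rose from 2566 ± 341 to 18760 ± 1290. Chlorophyll breakdown had 2 of 4 higher, SGR and NYC1, and 1 lower, NOL (adjusted p = 0.724). Dividing tissue markers had 2 of 18 higher and 5 lower (adjusted p = 0.321), the clock had 2 of 6 lower, PRR73 and PRR37 (adjusted p = 0.283), and the ribosome 2 of 19 higher and 6 lower (adjusted p = 0.321). The PHR family itself, with 3 genes, had 2 lower (adjusted p = 0.108). The 2 root markers measured were too few for the test, had a median of -0.24 and gave no call. Over all probe sets, 5870 rose and 6012 fell, 11882 in all (5700 and 4501 with arrays centred on their medians), and 13850 had an unadjusted p under 0.05. At least a 2-fold change was seen in 1953 that rose and 2900 that fell. Without the array labelled phr123 replicate 1, whose PHR3 signal lay above that of WT, 10865 were called.

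Comparing the mutants asked how far the triple mutant goes beyond each single mutant. SPX2 had 1890 ± 239 in phr123 and 1993 ± 57.5 in phr1 (n = 3), a difference that did not pass the test (-0.08, SE 0.118, limma adjusted p = 0.605). SPX1 was lower in phr123 than in phr1 by -2.22 on the log2 scale (adjusted p = 9.82e-11), and MGD2 by -4.46 (adjusted p = 7.02e-11). Against phr1, 5960 probe sets were higher and 6285 lower in phr123, 12245 in all. With arrays centred on their medians the balance turned to 8667 higher and 3685 lower. LIS was higher by 6.33 and CYP71Z7 by 5.92, and LOX1.1 was at least 21.8-fold, CPS4 at least 13.9-fold and LAC19 at least 12.7-fold higher. GER5 was lower by -6.18, and SPX5 was at least 24-fold, PHR2 at least 28.3-fold, BZIP06 at least 11.3-fold and TDL1B at least 9.96-fold lower. The adjusted p of these 10 genes ran from 1.84e-13 for GER5 to 0.000261 for LIS, whose difference was 5.33 without phr1 replicate 2 and 7.08 without phr1 replicate 3. Against phr3, 5461 were higher and 6253 lower, 11714 in all, which that centring turned to 6284 and 4151. CYP71Z7 was higher by 6.85, LEA19 by 5.48, RAA1 by 5.40 and LAC19 by 5.32, and LOX1.1 was at least 29.5-fold higher. In phr3 the means of RAA1 (38.03) and LAC19 (32.83) lay below the reporter level of all 3 arrays, so these sizes are uncertain. GER5 was lower by -6.14 and EXP7 by -5.35, and SPX5 was at least 37-fold, PHR2 at least 30.9-fold and TDL1B at least 8.89-fold lower. The adjusted p ran from 1.85e-13 for GER5 to 0.00112 for LAC19, whose difference was 6.09 without phr3 replicate 2.

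Jasmonate genes were higher in phr123 than in phr1, with 23 of 32 higher and 0 lower, or 23 and 1 adjusted over the list alone (camera adjusted p = 3.24e-06, and adjusted p = 0.0378 with an estimated correlation), and than in phr3, with 18 higher and 3 lower, or 20 and 3 over the list alone (camera adjusted p = 0.000295, and adjusted p = 0.045 with an estimated correlation). Pathogenesis-related genes were higher in phr123 in both comparisons, 11 of 12 each time (camera adjusted p = 4.04e-05 and 2.81e-05, and adjusted p = 0.0698 and 0.045 with an estimated correlation). SPX and PHO1 genes were lower, 5 of 7 against phr1 (camera adjusted p = 0.0296, and adjusted p = 0.124 with an estimated correlation) and 6 of 7 against phr3 (camera adjusted p = 0.00149, and adjusted p = 0.045 with an estimated correlation). Cell expansion genes were lower, 12 of 20 with 2 higher against phr1 and 9 of 20 with 2 higher against phr3 (camera adjusted p = 0.0149 and 0.0247, and adjusted p = 0.0698 and 0.0964 with an estimated correlation). Light reaction genes were lower too, 7 of 8 with 1 higher against phr1 and 6 of 8 against phr3, or 7 with 1 higher over the list alone (camera adjusted p = 0.0149 and 0.0247, and adjusted p = 0.307 and 0.354 with an estimated correlation). Heat shock genes were higher than in phr3, 21 of 41 with 5 lower, or 24 and 5 over the list alone (camera adjusted p = 0.0175, and adjusted p = 0.459 with an estimated correlation). The mean of that list relative to WT was 0.561 in the array labelled phr123 replicate 1 and -0.0375 and -0.034 in the other 2 phr123 arrays. Without that first array the median difference from phr3 went from 0.612 to 0.273, with 17 higher and 5 lower (camera adjusted p = 0.0358). PHR1 itself was higher in phr123 than in phr1 by 0.53 (adjusted p = 0.0159).

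The single mutants differed from each other most clearly in SPX2, lower in phr1 than in phr3 by -2.69 (SE 0.118, limma adjusted p = 8.85e-08, n = 3). CBF3 was lower in phr1 by -2.29 (adjusted p = 0.00428), ABA8OX1 by -2.32 (adjusted p = 0.00326), JAZ13 by -2.65 (adjusted p = 0.0213) and TIFY11a by -2.49 (adjusted p = 0.0231). CYCB1-1 was higher in phr1 by 1.76 (adjusted p = 0.00283), CYCB2-2 by 3.08 (adjusted p = 0.0164), LEA19 by 1.75 (adjusted p = 0.0198) and CDC2Os-3 by 1.58 (adjusted p = 0.0261), and HSFB2B was at least 2.91-fold higher (adjusted p = 0.0333). The calls that ended were those of JAZ13 without phr1 replicate 2 or phr3 replicate 2 or 3 (adjusted p from 0.057 to 0.107), TIFY11a without phr1 replicate 1 or 2 or phr3 replicate 2 or 3 (from 0.0844 to 0.102) and CYCB2-2 without phr1 replicate 2 or 3 (0.0835 and 0.0528). The same held for LEA19 without phr1 replicate 2 or 3 or phr3 replicate 1 or 2 (adjusted p from 0.0502 to 0.0902), CDC2Os-3 without phr1 replicate 1 or 2 or phr3 replicate 2 or 3 (from 0.0865 to 0.101) and HSFB2B without WT replicate 3, phr1 replicate 2 or 3 or any 1 phr3 array (from 0.0521 to 0.154). Without phr3 replicate 1 JAZ13 had -3.41 and TIFY11a -3.17, without phr3 replicate 2 JAZ13 had -1.93, and without phr3 replicate 3 CYCB2-2 had 3.81. The mean of CYCB2-2 in phr3, 34.47, lay below the reporter level of all 3 phr3 arrays. Median centring, quantile normalization, eBayes without a trend or a fit of phr1 and phr3 alone ended 1 or more of these calls (adjusted p from 0.0552 for CYCB2-2 to 0.154 for HSFB2B). Ribosome genes were higher in phr1 than in phr3, 3 of 19 over all tested and 16 adjusted over the list alone (camera adjusted p = 1.16e-12, and adjusted p = 0.175 with an estimated correlation), and so were dividing tissue markers, 3 of 18 or 7 over the list alone (camera adjusted p = 1.27e-05, and adjusted p = 0.0213 with an estimated correlation). Jasmonate genes were lower, 6 of 32 or 9 over the list alone (camera adjusted p = 4.29e-06, and adjusted p = 0.0213 with an estimated correlation), as were SPX and PHO1 genes, 2 of 7 (camera adjusted p = 0.000274, and adjusted p = 0.0213 with an estimated correlation), and clock genes, 2 of 6 (camera adjusted p = 0.0279, and adjusted p = 0.405 with an estimated correlation). The clock list mean relative to WT was -0.404 in phr1 replicate 1, which stood apart. In phr1 replicates 2 and 3 it was -0.0864 and -0.00714, within the phr3 range of -0.0961 to 0.192. In all, 194 probe sets were higher and 285 lower in phr1. Their total fell to 162 without phr1 replicate 2, 240 without phr3 replicate 2, 210 without phr3 replicate 3, 278 with arrays centred on their medians (59 higher and 219 lower), 169 with eBayes without a trend and 294 in a fit of phr1 and phr3 alone.

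The departure from the sum asked whether phr123 differs from the phr1 and phr3 changes added together. It holds the loss of PHR2 and any joint effect of losing PHR1 and PHR3. It also holds any joint effect of losing PHR2 with either or both of them. These cannot be parted here. MGD2 departed by -4.10 on the log2 scale (limma adjusted p = 1.39e-08), SPX1 by -2.14 (SE 0.104, adjusted p = 1.39e-08), SPX3 by -1.87 (adjusted p = 0.00241), MGD3 by -1.58 (adjusted p = 1.02e-06), PHO1;3 by -1.20 (adjusted p = 0.0114) and PT4 by -0.80 (adjusted p = 0.00163). SPX2 did not depart (-0.10, SE 0.166, adjusted p = 0.707). AOX1a departed upward by 3.42 (adjusted p = 2.76e-08) and PT8 by 1.47 (adjusted p = 3.03e-06). CYP71Z7 departed upward by 7.19 (adjusted p = 3.44e-07) and LEA19 by 5.21 (adjusted p = 3.15e-06), and GER5 departed by -6.07 (adjusted p = 2.52e-11). LAC19 (adjusted p = 0.00234), LOX1.1 (adjusted p = 0.000162) and CPS4 (adjusted p = 0.00482) departed upward too. PHR2 (adjusted p = 2.56e-08), TDL1B (adjusted p = 0.000191), SPX5 (adjusted p = 0.000124) and BZIP06 (adjusted p = 0.00444) departed downward. LAC19, LOX1.1 and CPS4 lay at or below the reporter level in all WT and phr1 arrays, and PHR2, TDL1B, SPX5 and BZIP06 in all phr123 arrays, so no size is given for them. SPX3 lay near that level in phr123, so the size of its departure is uncertain. In all, 3869 probe sets departed upward and 4703 downward, 8572 together. Centring on medians turned the balance to 5952 and 2187. Pathogenesis-related genes departed upward, 9 of 12 with 0 downward, or 10 and 0 adjusted over the list alone (camera adjusted p = 1.29e-05, and adjusted p = 0.047 with an estimated correlation), jasmonate genes 17 of 32 with 1 downward, or 19 and 1 (camera adjusted p = 0.000191, and adjusted p = 0.047 with an estimated correlation) and heat shock genes 20 of 41 with 1 downward, or 23 and 4 (camera adjusted p = 0.00117, and adjusted p = 0.416 with an estimated correlation). The array labelled phr123 replicate 1 stood apart in the heat shock list (mean 0.561 relative to WT, against -0.0375 and -0.034), and without it 19 departed upward and 1 downward (camera adjusted p = 0.00132). Lists that departed downward were cell expansion, 8 of 20 with 1 upward, or 10 and 1 (camera adjusted p = 0.00495, and adjusted p = 0.047 with an estimated correlation), light reactions, 5 of 8 or 7 (camera adjusted p = 0.0183, and adjusted p = 0.351 with an estimated correlation), SPX and PHO1, 4 of 7 (camera adjusted p = 0.0318, and adjusted p = 0.142 with an estimated correlation), and membrane lipids, 2 of 3 (camera adjusted p = 0.0351, and adjusted p = 0.287 with an estimated correlation).

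Many changes were shared between mutants. The phr1 and phr3 calls shared 64 probe sets that rose and 30 that fell, with 0 in opposite directions, where independent lists of those sizes would share 1.61 and 1.02. The r of their log2 changes was 0.484 across probe sets, against 0.5 in simulated groups with no effect that share the WT arrays, and the covariance was 0.102 against 0.0632. The count of shared calls was 61 without WT replicate 1, 55 without WT replicate 2, 52 without phr1 replicate 2, 61 without phr1 replicate 3 and 56 with arrays centred on their medians. With phr123, phr1 shared 95 that rose and 89 that fell, with 28 in opposite directions (26.3 and 29.2 for independent lists, r 0.216 against 0.499 simulated, covariance 0.104 against 0.0632). For phr3 and phr123 these were 253, 129 and 54 (73.9 and 43.9 for independent lists, r 0.312 against 0.499 simulated, covariance 0.154 against 0.0633). Probe sets are not independent replicates, and the shared WT arrays can add to these numbers. With a different single WT array as the control of each mutant, in the 6 possible ways and with the spread taken from the mutants, the phr1 and phr3 calls shared 23 to 29 in the same direction and 0 in opposite ones. The covariance of their changes was then 0.031 to 0.0418. The covariance with phr123 was 0.0208 to 0.0557 for phr1 and 0.0735 to 0.104 for phr3. A total of 74 probe sets changed in the same direction in all 3 mutants, 52 up and 22 down, and 17 to 23 did so with separate WT arrays, with at most 1 of mixed direction. The largest rises among the 74 came from probe sets whose gene had no symbol or that had no single gene named. Among those with a symbol were RR9 (1.49, 2.00 and 2.32 in phr1, phr3 and phr123), BGLU13 (1.60, 1.22 and 1.58), SPX3 (-1.67, -1.18 and -4.72), HSFB2A (-0.86, -1.85 and -2.00) and RR6 (1.04, 0.84 and 1.54), and, chosen after its values were seen, RR4 (0.70, 0.83 and 1.42). The phr1 call of RR4 ended with arrays centred on their medians (adjusted p = 0.178), those of SPX3 and HSFB2A in phr1 and of SPX3 in phr3 ended without single arrays as given above, and the rest kept theirs when any 1 array was left out.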

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

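The tests of a mixed or swapped sample, of the hour of sampling and of separate WT arrays were chosen only after the results they concern had been seen, and the other tests before.

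Some reporter control probe sets of the array, which were left out of the tests, held a signal above the level of WT. They were also left out of the 95th percentile that sets the reporter level. Of 64 reporter controls, 3 probe sets of a single sequence that is not a rice gene had 422 ± 43.7, 124 ± 66.4 and 181 ± 50.2 in phr123 (mean ± SD, n = 3). The WT means were 55.5, 9.5 and 30.7, and the highest single arrays outside phr123 had 119, 34.2 and 63.9. The limma adjusted p over the reporters, after a pseudocount of 16 was added, was 0.00211, 0.00718 and 0.0112. No explanation for this signal was tested.

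The PHR3 signal of the array labelled phr123 replicate 1 was 270% of the WT mean, against a genotype that should lack PHR3. WT RNA mixed into that sample, or a label swapped with a WT, phr1 or phr3 sample, would bring PHR2 along, but PHR2 lay at 0.981% of the WT mean there, SPX5 at 0.173% and MGD2 at 3.06%. A defect of the whole array may still play a part. In that array 375 probe sets lay at least 4-fold from both other arrays of its genotype, where the highest other array had 270, which is neither over 1.5 times that number nor at or under it. The design gives no biological explanation for a difference between replicates, and none was tested.

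A total of 74 probe sets changed in the same direction in all 3 mutants. Noise of the WT arrays shared by the 3 comparisons is not the whole cause. With a different WT array as the control of each mutant, the lowest of 6 counts was 17, where independent lists would share at most 0.0798. A single WT array has no spread of its own, so the spread came from the replicates of the mutants. A spread estimate shared by the 3 comparisons can also lift this count, but it favours no direction, and at most 1 probe set passed in all 3 with mixed directions. Such noise may still add to the 74. Simulations without effects, with a highest count of 0, cannot tell how much, because they hold hardly any calls to share. A difference common to all 3 WT arrays would pass this test and was not tested apart from the mutations. A chromosome segment that differs between the WT plants and the mutants could also give shared changes. Only probe sets with 1 gene named could enter the test of this, which left 51 genes. Probe sets with no single gene named, which held many of the largest shared rises, could not. The share of the 51 genes with another of them within 10 gene positions was 7.84%, equal to the 95th percentile of 1000 random sets, 7.84%, so this stays open. An effect of losing any PHR gene, which the design names, also stays open and was not tested apart from it.

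The jasmonate list lay higher in phr3 than in WT (camera adjusted p = 0.000319, and adjusted p = 0.108 with an estimated correlation). A single phr3 array does not carry this, as the lowest of the 3 phr3 list means, 0.277, lay 0.232 above the highest of the 3 WT means. A different hour of sampling may contribute and cannot be told apart from genotype, because the labels give no hour. Among 6 clock genes the largest difference was -0.433 (PRR1, SE 0.475), and PRR95 (0.424) passed in a fit of phr3 and WT alone (adjusted p = 0.0359). An effect of losing PHR3 also stays open.

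Other splits of the same arrays were counted for each comparison. For each pair of genotypes only 10 splits exist, too few for a share under 0.05, and 1 of 10, the real one, gave a count as large as the real one. The real count and the highest other were 267 and 1 for phr1 against WT, 569 and 0 for phr3 against WT and 11882 and 0 for phr123 against WT. They were 12245 and 0 for phr123 against phr1 and 11714 and 0 for phr123 against phr3. For phr1 against phr3 the highest other was 1. Every other split of a pair mixes both genotypes and so puts any difference between them into the spread. Few calls can pass then, so these low counts do not exclude chance. For the departure from the sum, 1 of 100 groupings, the real one, gave a count as large (8572). The highest other was 7695, from 1 of 2 groupings that kept the 3 phr123 arrays together, and the highest among those that parted them was 1. This points to a structure of the samples in which phr123 stands apart. Groupings that part the phr123 arrays put the large differences of phr123 into the spread, so few calls can pass. The share of 1 in 100 therefore does not exclude chance for the departure itself. Only 2 of the 99 groupings drawn kept these arrays together, with counts of 6760 and 7695, too few to tell.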

How the results depend on the processing

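The list medians under other scalings, and the lists without single phr123 arrays in comparisons with the single mutants and in the departure, were chosen after seeing the data, and the other alternatives before. Signal over background limits what can be read, as 47.5% to 57.1% of probe sets lay above the reporter level of their array. The array medians used for centring lie near that level, so centring follows background as well as transcripts. The cause of the changes below was not tested, except that a 2-fold requirement lowers counts by its construction.

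The median of the ribosome list in phr1 turned sign, going from 0.116 to -0.078 with arrays centred on their medians. That centring also gave 298 probe sets in phr3, 278 between phr1 and phr3, 56 shared calls of the single mutants and -0.462 for PHR1 in phr123 (adjusted p = 0.0802). Scaling shifted the median of all probe sets by up to 0.19 in phr1, 0.29 for phr123 against phr1, 0.17 for phr123 against phr3, 0.12 for phr1 against phr3 and 0.37 for the departure. With centring, probe sets up and down were 62 and 182 in phr1 (128 and 139 without it), 8667 and 3685 for phr123 against phr1 (5960 and 6285), 6284 and 4151 for phr123 against phr3 (5461 and 6253), 59 and 219 for phr1 against phr3 (194 and 285) and 5952 and 2187 for the departure (3869 and 4703).

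With eBayes without a trend, 121 probe sets were called in phr1, 299 in phr3 and 169 between them. A change of at least 2-fold held for 88 in phr1, 207 in phr3, 4853 in phr123, 4936 for phr123 against phr1, 4662 against phr3, 1.2e+02 for phr1 against phr3 (61 higher and 62 lower) and 4479 for the departure. A fit of only the genotypes compared gave 294 between phr1 and phr3, and PHR3 in phr3 passed at -2.34 (adjusted p = 0.0011). With an estimated correlation, 1 list passed in phr1, 0 in phr3 and 1 in phr123, against 4 in each with the preset one.

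Leaving out 1 array at a time gave 128 to 384 probe sets in phr1, 331 to 718 in phr3, 162 to 580 between them, 10415 to 12249 in phr123, 10767 to 12165 for phr123 against phr1, 10284 to 12088 against phr3 and 7623 to 8189 for the departure. The counts of 384, 718 and 580, and the 139 shared calls below, all came without the array labelled phr123 replicate 1. That array entered these comparisons only through the spread estimated across all genotypes. In phr1 the count was 169 without WT replicate 1, 146 without WT replicate 2, 128 without phr1 replicate 2 and 164 without phr1 replicate 3. In phr3 it was 331 without WT replicate 2, 378 without WT replicate 3, 347 without phr3 replicate 2 and 341 without phr3 replicate 3. Between phr1 and phr3 it was 162 without phr1 replicate 2, 240 without phr3 replicate 2 and 210 without phr3 replicate 3. Shared calls ran from 52 to 139, with 61 without WT replicate 1, 55 without WT replicate 2, 52 without phr1 replicate 2 and 61 without phr1 replicate 3, and their r from 0.428 to 0.561. Lists that passed ran from 2 (without WT replicate 2) to 5 in phr1, from 4 to 5 in phr3 and from 4 to 8 (without the array labelled phr123 replicate 1) in phr123. The heat shock list, whose mean stood apart in the array labelled phr123 replicate 1, passed without any 1 phr123 array, with adjusted p from 0.00326 to 0.0358 for phr123 against phr3 and from 0.000193 to 0.00132 for the departure, and so did every other list that had passed there or against phr1. PHR1 ran from -1.2 to -0.948 in phr1 and from -0.678 to -0.406 in phr123, where WT replicate 3 and the array labelled phr123 replicate 1 each ended the call. PHR3 ran from -2.57 to -2.05 in phr3, and in phr123 from -1.62 without the array labelled phr123 replicate 1 to 0.048, of the other sign, without phr123 replicate 3 (adjusted p = 0.959). PHR2 kept its call in phr123 in both probe sets, and as these lay at or below the reporter level there, no range is given. Single-gene calls were checked this way also for genes that the text does not name. With those of PHR1, PHR2 and PHR3 against WT aside, 17 of 37 in phr1, 13 of 39 in phr3, 2 of 107 in phr123 and 6 of 10 between phr1 and phr3 ended at least once, and 0 of 10 in each other comparison.

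With the repeat number as a block, counts were 235 in phr1, 502 in phr3, 11600 in phr123, 11926 for phr123 against phr1, 11433 against phr3, 390 between phr1 and phr3 and 8235 for the departure. Of the single-gene calls checked, the block ended 4 of 37 in phr1 and 4 of 39 in phr3. Among them were ATCase and ARP9 in phr1 (limma adjusted p = 0.0792 and 0.0504). In phr3 they included CYCB2-2, LEA19 and WRKY24 (limma adjusted p = 0.0728, 0.0702 and 0.0515). The repeat numbers did not pair the arrays, as deviations of arrays with the same number had r from -0.0464 to 0.0323 over 18 pairs.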

Other observations

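The gene families here were chosen after their values were seen, and 100 families named by a shared symbol were tested with camera against all other genes. In phr123, 8 of 9 cellulose synthase genes (CESA) fell and 0 rose (median -1.25, adjusted p = 0.000852, and adjusted p = 0.331 with an estimated correlation), among them CESA5, from 2934 to 492.7 (-2.60, limma adjusted p = 2.66e-07), and CESA6, from 4579 to 1309 (-1.82, limma adjusted p = 1.64e-08). Of 22 Aux/IAA genes 14 fell and 1 rose, of 27 kinesin genes (KIN) 17 fell and 2 rose, and of 24 homeobox genes (HOX) 12 fell and 2 rose (adjusted p = 0.00184, 0.00184 and 0.0208, and adjusted p = 0.233, 0.331 and 0.323 with an estimated correlation). All 6 Rac GTPase genes fell (adjusted p = 0.0051, and adjusted p = 0.323 with an estimated correlation), with Rac6 from 4108 to 977.5. In phr3, 3 of 5 DREB genes and 3 of 6 WRKY genes rose and 0 fell (adjusted p = 0.00392 and 0.00974, and adjusted p = 0.239 for both with an estimated correlation). Of 6 response regulators (RR), 3 rose in phr1 and 3 in phr3, with 0 lower (adjusted p = 4.86e-08 and 1.33e-06, and adjusted p = 0.0567 and 0.107 with an estimated correlation).

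Some genes without a symbol had the largest changes, and these too were chosen after their values were seen. LOC4331398 had 36.53 ± 5.78 in WT, 3925 ± 512 in phr1, 3882 ± 120 in phr3 and 1828 ± 2310 in phr123 (mean ± SD, n = 3), at least 70.7-fold higher in phr1 (limma adjusted p = 4.68e-05) and at least 70.3-fold in phr3 (adjusted p = 3.09e-05). Its probe sets were among the 74 that changed in the same direction in all 3 mutants. In phr123, LOC4325422 rose from 685.8 ± 158 to 46290 ± 4760 (6.10, adjusted p = 1.05e-09) and LOC4337246 from 89.03 ± 17.4 to 6477 ± 1240 (6.19, adjusted p = 1.76e-09). LOC4327106 fell from 29870 ± 1710 to 103.2 ± 98.3 (-8.65, adjusted p = 6.38e-09) and LOC4348119 from 21440 ± 827 to 65.53 ± 20.2 (-8.40, adjusted p = 3.58e-13). The fall of LOC4327106 was -9.41 without the array labelled phr123 replicate 1 and -7.98 without phr123 replicate 3.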
